A study of Homo sapiens with 6 samples.

How the data were processed

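NCI-H292 cells were profiled by RNA sequencing in 6 libraries, 3 from cells with a knockdown of SH3PXD2A-AS1 and 3 from negative control cells. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and accepted by purity and integrity limits. Messenger RNA was then selected with oligo(dT) beads, copied with random hexamer primers, size selected, amplified by PCR and sequenced as paired reads with an Illumina TruSeq RNA preparation. Poly(A) selection lowers RNAs without a tail, so levels of small nuclear RNAs and of most histone messages depend on how complete the selection was. Whether the library kit or the counting kept strand is not given in the sources used here. Whether reads of a gene were kept apart from those of an antisense RNA over the same bases is therefore unknown. The knockdown reagent and its delivery are not described beyond the words knockdown, negative control and vector control in the labels and series text.

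The authors deposited 1 table of length-scaled transcript levels (TPM), with a TPM column for each library, a gene length column and gene annotations. TPM divides the reads of each gene by its length and scales each library to the same total, so that a rise in abundant genes lowers all others. Per the submitters' processing notes, fastp, HISAT and RSEM were used, with no versions or roles given. The same notes name the genome build GRCm38.p5, which is a mouse build, while 58883 of the 60027 gene IDs in the table are human Ensembl IDs. The build behind the deposited values is therefore unsettled, and no coordinates were taken from the table. Another 1144 IDs carry the prefix MSTRG and have no gene name. 1 line of the table was empty and is not reported here. Gene symbols came from the annotations deposited with the TPM values. A separate gene name table, in which 58471 IDs were found, was used to look up list symbols that those annotations lacked. Gene positions and types came from GENCODE 29 on GRCh38, in which 58610 IDs were found by Ensembl ID. All 6 TPM columns were matched to samples by the group and replicate number in their names. TPM values keep no sequencing depth, so the depth of each library is unknown and no counting interval could be given. The precision of each value is therefore the spread between the 3 libraries of a group.

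Genes with a mean TPM of at least 1 over the 6 libraries (15755 of 30849 with a TPM above 0) were tested with limma (version 3.58.1, R 4.3.3) on log2(TPM + 1), with a prior spread that follows the mean, between the groups and without covariates. P-values are two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, knockdown minus negative control, which understates the change of low genes. SH3PXD2A-AS1 lies under the filter and was fitted without it, and its mean TPM was also compared by an exact permutation test. In all, 38 gene lists fixed before the data were examined were looked up, and 34 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, stand beside it. Of the 995 list entries, 6 were not found in the table. The table's own GO and KEGG terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test, separately for genes that rose and fell, against the 13592 tested genes with any term.

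The text names SH3PXD2A-AS1, SH3PXD2A and DHX9. It also draws on the 10 largest rises and falls among genes with an adjusted p under 0.05, a mean TPM of at least 5 in the higher group, no overlap between groups and a gene symbol. For each list with a called member or a called test, it draws on up to 4 tested members with the smallest p. CCND1, CCNE1, CDK2, CDK4, CDK6, CDKN1A and CDKN1B are named whatever their p. Genes named outside this rule are said to be chosen after their values were seen.

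The tests were run first on simulated data. In a simulated comparison of 3 against 3 libraries with the real means and spreads of 15755 genes, 200 genes were changed. Of the 50 changed by each size, the test recovered 3 at 1.2-fold, 24 at 1.5-fold, 38 at 2-fold and 41 at 4-fold, and it called 5 of 15555 unchanged genes. Far fewer genes were changed than the 2327 called in the data, and noise was drawn for each gene alone. No shift of a whole library was simulated, so these rates need not hold for the data. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean TPM of 5, median ratio scaling, quantile normalization, rescaling without mitochondrial and ribosomal protein genes, a prior spread without trend, array weights, the replicate number as a block, and leaving out each library in turn. Removal of each library's trend with gene length and GC content by lowess was added after seeing the data. Words of 7 bases in annotated 3′ untranslated regions were searched with Python 3.11.15 and NumPy 2.4.6, pandas 2.3.3 read the tables and Matplotlib 3.10.9 drew the plots.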

Results

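Polyadenylated RNA was measured in NCI-H292 cells, a human line from a mucoepidermoid carcinoma of the lung. There were 3 libraries from cells with a knockdown of SH3PXD2A-AS1, a long noncoding RNA, and 3 from negative control cells. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Depth is unknown because TPM values keep none. A TPM above 0 was listed for 23162 to 25910 genes per library, and 15432 to 15883 genes reached 1 TPM. The series title links SH3PXD2A-AS1 to proliferation, the cell cycle and the RNA helicase DHX9, and the comparison asked which genes differed between knockdown and control cells.

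SH3PXD2A-AS1 was low in every library, and its level did not separate the groups. It stood at 0.96, 0.75 and 0.51 TPM in negative control replicates 1 to 3 and at 0.37, 0.68 and 0.44 TPM in knockdown replicates 1 to 3. The means were 0.740 ± 0.225 and 0.497 ± 0.163 TPM (SD, n = 3), or 67.1% of control, and knockdown replicate 2 lay above negative control replicate 3. An exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest p this design allows. The limma log2 fold change was −0.21 (SE 0.14, adjusted p = 0.517 without the filter on mean TPM). The gene (ENSG00000280693) lies on chromosome 10 at 103745966 to 103755423 on the plus strand of GRCh38, inside SH3PXD2A (ENSG00000107957, 103594027 to 103855543, minus strand), and its exons share 0 bases with SH3PXD2A exons. Reads from unspliced SH3PXD2A RNA could enter its value if strand was not kept. SH3PXD2A, which encodes an invadopodia scaffold, stood at 7.31 ± 2.02 TPM in control and 7.15 ± 0.474 TPM in knockdown libraries (limma adjusted p = 0.995). DHX9 (ENSG00000135829, chromosome 1 at 182839369 to 182887751, plus strand) stood at 61.0 ± 2.28 and 61.7 ± 2.67 TPM (limma adjusted p = 0.881).

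**Figure D1:**
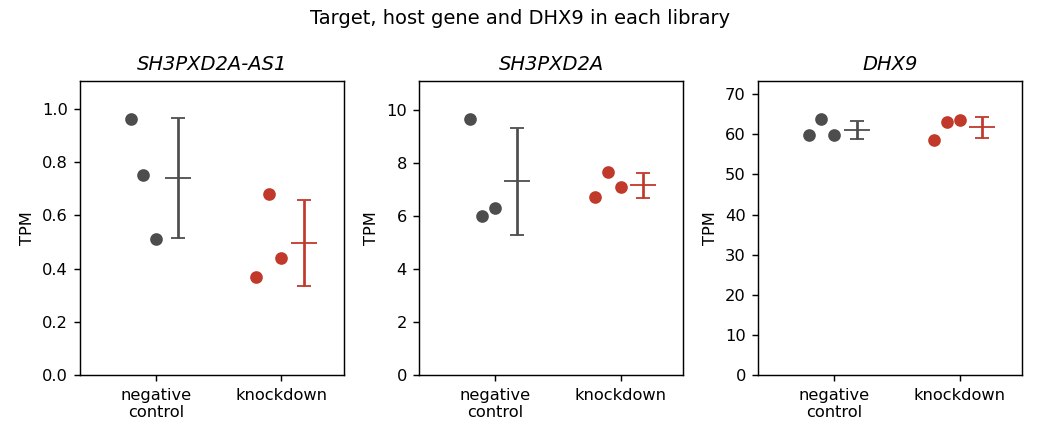
TPM of SH3PXD2A-AS1, SH3PXD2A and DHX9 in the 3 negative control (grey) and 3 knockdown (red) libraries, each point a library and each bar the mean ± SD. For SH3PXD2A-AS1 the knockdown library at 0.68 TPM lies above the control library at 0.51 TPM.

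Knockdown cells had higher levels of interferon-stimulated and cytokine genes and lower levels of mitosis genes and of genes encoded in mitochondrial DNA. Of 15755 genes tested, 2327 changed, of which 1780 rose and 547 fell (limma, adjusted p under 0.05). Most changes were small: 161 genes rose and 20 fell at least 2-fold, and 1264 of the rises and 431 of the falls were under 1.5-fold. An unadjusted p under 0.05 was reached by 4789 genes. The groups did not overlap for 36.5% of genes, where the chance for a single gene is 10%. Genes can vary together across libraries, so the share found by chance in 1 grouping can lie far from 10%. The median log2 fold change of all genes tested was 0.08. The split of calls depended on scaling: 1012 rose and 996 fell after median ratio scaling, 1001 and 980 after quantile normalization, 1083 and 862 after rescaling without mitochondrial and ribosomal protein genes, and 1110 and 1152 with length and GC trends removed, a fit limited to 14746 genes. The lists in the following paragraphs are described by their members. Each of the 20 lists with a called test kept the sign of its median in these 4 fits, and 17 were called in all 4. The signs were largely bound to hold, since these fits mainly take a small shared rise out of all genes.

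Interferon-stimulated genes had the highest median of the 34 lists tested. Of 36 members, 35 rose (36 adjusted over the list alone), with a median log2 fold change of 1.51. IFIT2, an antiviral RNA-binding protein, rose from 15.6 ± 1.58 to 114 ± 11.9 TPM (SD, n = 3; limma log2 fold change 2.79, SE 0.10, adjusted p = 0.000111). OASL, an interferon-induced antiviral protein, rose from 6.53 ± 1.82 to 82.4 ± 2.41 TPM (limma adjusted p = 0.000209). BST2, which tethers budding virions, rose from 11.4 ± 2.49 to 112 ± 11.1 TPM (limma adjusted p = 0.000209). IFI27, IFI6 and ISG15, the ubiquitin-like modifier, reached 664 ± 104, 488 ± 32.9 and 1309 ± 78.0 TPM from 52.1 ± 13.8, 59.4 ± 15.6 and 185 ± 37.2 TPM. The interferon genes IFNB1 and IFNL1 rose from 0.137 ± 0.121 and 0.397 ± 0.473 TPM to 6.56 ± 2.75 and 8.38 ± 1.97 TPM (limma adjusted p = 0.00196 and 0.00169). Reads of IFNL1 may be shared with its near copies. The list differed from other genes by camera with the preset correlation (adjusted p = 3.59e-29) but not with an estimated correlation (adjusted p = 0.202), and fry called it (adjusted p = 0.000473).

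NF-kB and cytokine genes rose alongside. Of 23 members, 17 rose and none fell (17 adjusted over the list alone), with a median log2 fold change of 0.58 (camera adjusted p = 2.25e-09; adjusted p = 0.203 with an estimated correlation). The cytokine genes CSF2 and IL6 rose from 7.71 ± 0.989 to 25.4 ± 2.85 TPM and from 64.9 ± 7.19 to 168 ± 15.0 TPM. TNFAIP3, a feedback inhibitor of NF-kB, rose from 73.2 ± 7.88 to 175 ± 12.1 TPM, and the adhesion gene ICAM1 from 69.2 ± 2.07 to 118 ± 2.54 TPM. Among 28 apoptosis regulators, 8 rose (11 adjusted over the list alone). PMAIP1, a BH3-only death inducer, rose with a log2 fold change of 1.11 (SE 0.06, limma adjusted p = 0.000239). CFLAR and BIRC3, which restrain cell death, rose as well, with log2 fold changes of 0.79 and 0.66 (SE 0.09 for both). The apoptosis list was called by camera (adjusted p = 0.000415; adjusted p = 0.203 with an estimated correlation) and had 5 rises after median ratio scaling.

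**Figure D2:**
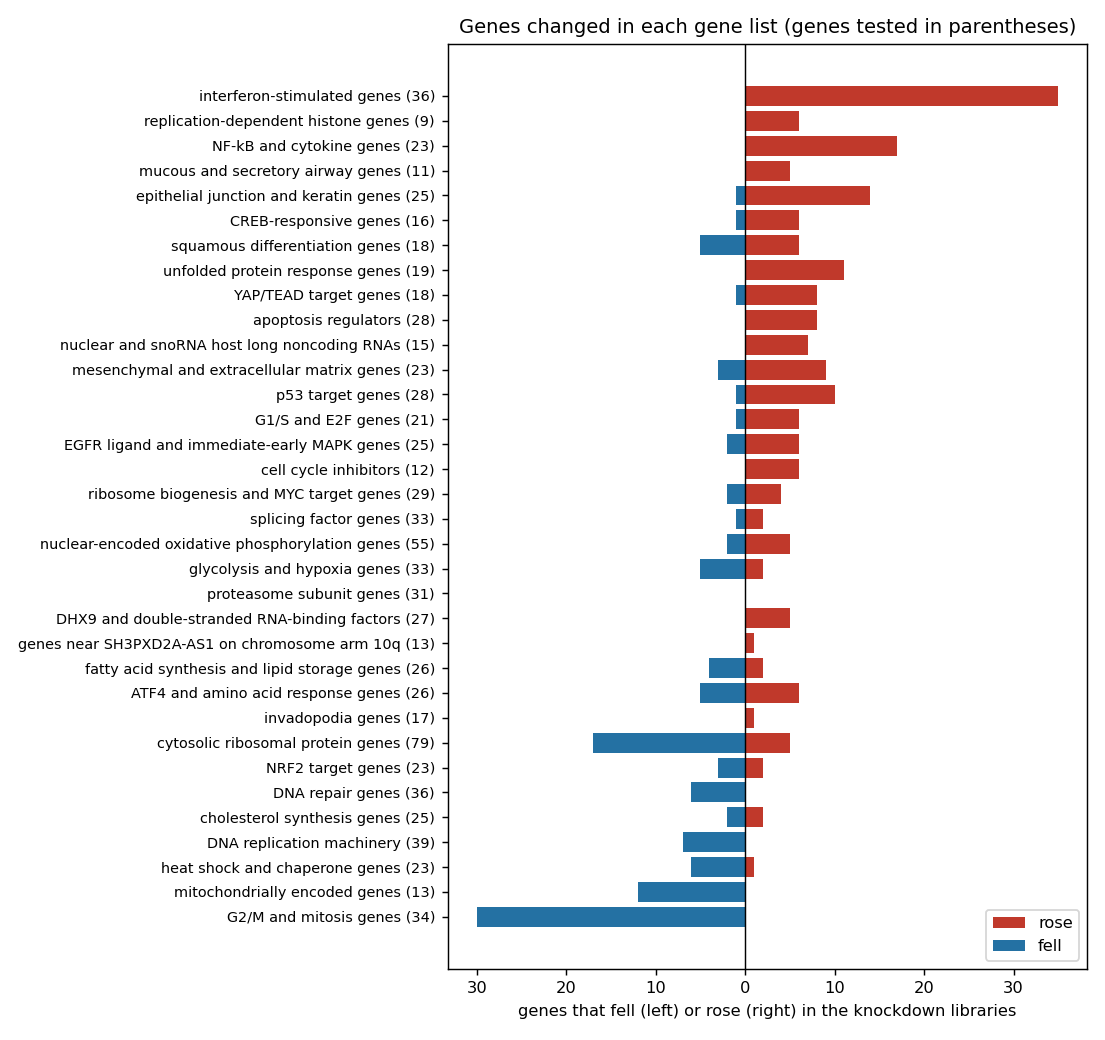
Number of genes that fell (blue, left) or rose (red, right) in knockdown libraries at a limma adjusted p under 0.05 for each of the 34 gene lists tested, ordered by median log2 fold change, with the number of genes tested in parentheses. Interferon-stimulated genes (35 of 36 rose) and G2/M genes (30 of 34 fell) stand at the ends.

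Genes of G2 and mitosis fell. Of 34 members, 30 fell and none rose (34 fell adjusted over the list alone), with a median log2 fold change of −0.55 (camera adjusted p = 1.23e-35; adjusted p = 0.0495 with an estimated correlation). The mitotic kinesin gene KIF20A fell from 69.5 ± 1.96 to 35.2 ± 0.327 TPM (limma log2 fold change −0.96, SE 0.05, adjusted p = 0.000199). CCNB1, which encodes cyclin B1, fell from 188 ± 5.39 to 114 ± 5.57 TPM. CDC20, an activator of the anaphase-promoting complex, fell from 205 ± 2.45 to 137 ± 4.20 TPM, and KIF2C, another kinesin gene, fell from 107 ± 3.39 to 69.8 ± 1.83 TPM. PIMREG and PSRC1, both linked to mitosis, were among the 10 largest falls, from 28.1 ± 1.77 to 13.3 ± 0.997 TPM and from 31.6 ± 1.14 to 15.7 ± 0.830 TPM.

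Other parts of the cell cycle moved less or in the other direction. DNA replication genes had a median log2 fold change of −0.12. Of 39 members, 7 fell (11 adjusted over the list alone; camera adjusted p = 3.18e-07, and adjusted p = 0.0469 with an estimated correlation). RRM1, a ribonucleotide reductase subunit, fell from 104 ± 1.97 to 75.7 ± 3.36 TPM. Of 36 DNA repair genes, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00189, and adjusted p = 0.323 with an estimated correlation). PRKDC and PARP1 were among them, with log2 fold changes of −0.35 and −0.31 (SE 0.05 for both). Of 21 G1/S and E2F genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.323). Cyclin A2, encoded by CCNA2, fell from 75.9 ± 3.60 to 51.3 ± 2.86 TPM, while the D cyclin genes CCND2 and CCND3 rose from 54.3 ± 0.982 to 72.6 ± 2.84 TPM and from 49.7 ± 3.68 to 65.7 ± 1.81 TPM. CCND1 stood at 92.3 ± 1.72 and 110 ± 7.46 TPM (limma adjusted p = 0.0369) and CDK6 at 21.4 ± 1.03 and 26.4 ± 1.17 TPM (limma adjusted p = 0.0286). Both calls were lost after median ratio scaling, with log2 fold changes of 0.15 and 0.20. CCNE1, CDK2 and CDK4 did not pass the test, with log2 fold changes of 0.21 (SE 0.10), −0.09 (SE 0.06) and −0.12 (SE 0.06). Among 12 cell cycle inhibitors, 6 rose (6 adjusted over the list alone; camera adjusted p = 0.0756). CDKN1B, which encodes p27, rose from 60.6 ± 6.07 to 87.9 ± 4.09 TPM. CDKN1A, which encodes p21, stood at 413 ± 13.0 and 466 ± 10.3 TPM (limma adjusted p = 0.03), a call lost after median ratio scaling (log2 fold change 0.08). The p53 target list had 10 rises and 1 fall among 28 members (11 and 1 adjusted over the list alone; camera adjusted p = 0.00686, and adjusted p = 0.202 with an estimated correlation). PLK2, a polo-like kinase gene, rose from 219 ± 7.19 to 320 ± 8.30 TPM. Of 9 replication-dependent histone genes, 6 rose (8 adjusted over the list alone; camera adjusted p = 0.000106, and adjusted p = 0.0807 with an estimated correlation). HIST2H2BE rose from 16.9 ± 0.345 to 28.5 ± 0.729 TPM. Poly(A) selection lowers messages without a tail, so the levels of most histone messages depend on how complete it was. Median ratio scaling gave 14 falls in the DNA replication list, 8 falls in the DNA repair list, 3 rises and 2 falls in the G1/S list, 4 rises among inhibitors, 5 rises and 1 fall among p53 targets and 5 rises among histone genes. The genes of the replication-dependent histone list alone took 0.0117% to 0.0122% of TPM in control and 0.0183% to 0.0185% in knockdown libraries.

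**Figure D3:**
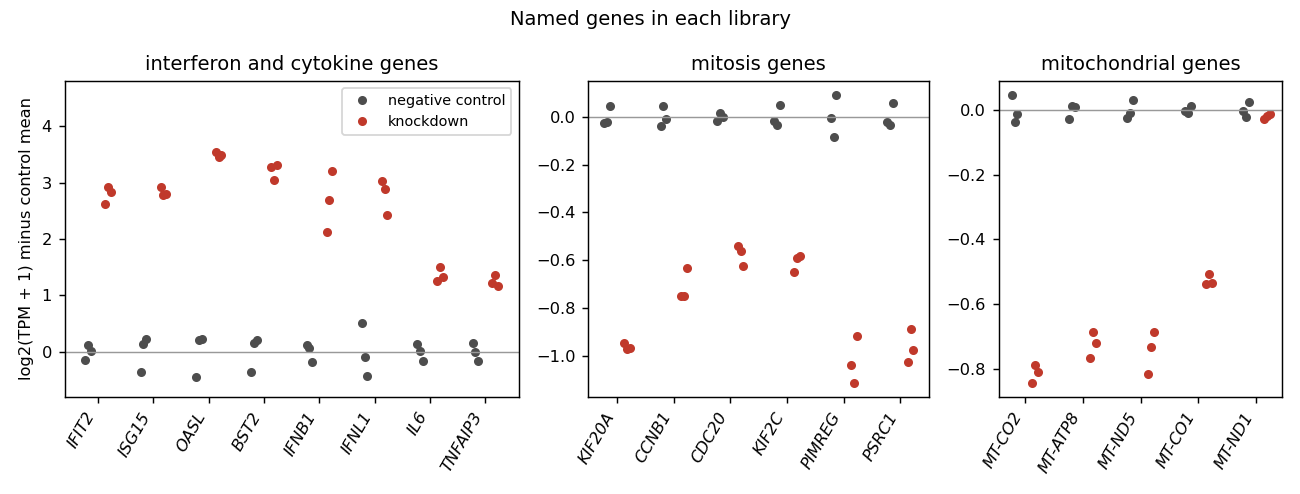
Level of named genes in each library, as log2(TPM + 1) minus the mean of the 3 negative control libraries, with control libraries in grey and knockdown libraries in red. Each panel has its own vertical scale. In every gene shown except MT-ND1 the 2 groups do not overlap.

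Genes encoded in mitochondrial DNA fell. Of 13, 12 fell (12 adjusted over the list alone), with a median log2 fold change of −0.54 (camera adjusted p = 6.65e-21; adjusted p = 0.0469 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, fell from 15904 ± 465 to 9043 ± 171 TPM and MT-ND5, a subunit of complex I, from 1998 ± 39.8 to 1192 ± 54.2 TPM. MT-ATP8 fell from 23096 ± 353 to 13965 ± 390 TPM, a change that quantile normalization sets to 0 for this abundant message. MT-ND1, chosen after its value was seen because it did not fall with the rest, stood at 4105 ± 65.9 and 4053 ± 24.9 TPM (limma adjusted p = 0.729). Genes of mitochondrial DNA took 10.7% to 10.9% of TPM in control and 7.20% to 7.40% in knockdown libraries. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of 0.04, with 5 rises and 2 falls among 55 (6 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.812). After median ratio scaling 1 rose and 6 fell, with a median of −0.05.

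**Figure D4:**
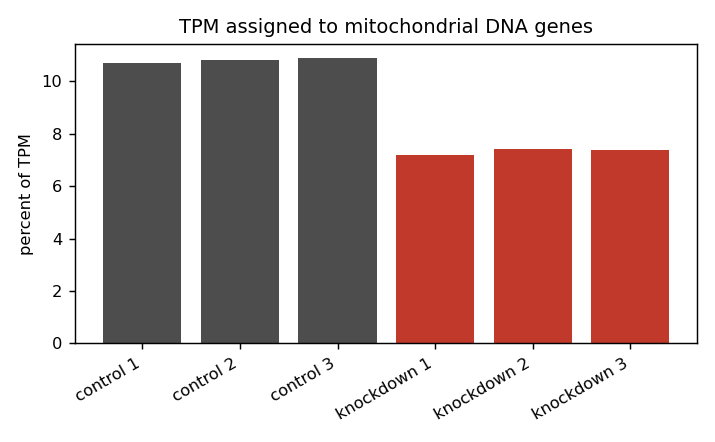
Percent of TPM assigned to genes of mitochondrial DNA in each library, with negative control libraries in grey and knockdown libraries in red. The control libraries lie between 10.7% and 10.9% and the knockdown libraries between 7.20% and 7.40%.

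Some epithelial genes rose. Of 25 junction and keratin genes, 14 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 6.83e-07; adjusted p = 0.0469 with an estimated correlation). The tight junction gene CLDN4 rose from 450 ± 16.7 to 889 ± 50.8 TPM, the membrane protease gene ST14 from 132 ± 4.42 to 213 ± 8.96 TPM and the keratin gene KRT7 from 654 ± 25.2 to 887 ± 20.7 TPM. Of 11 mucous and secretory airway genes, 5 rose (6 adjusted over the list alone; camera adjusted p = 0.00651, and adjusted p = 0.203 with an estimated correlation). The mucin gene MUC16 rose from 21.8 ± 0.236 to 37.9 ± 0.973 TPM and MUC4 from 53.2 ± 0.583 to 75.1 ± 2.27 TPM. Squamous differentiation genes went both ways, with 6 rises and 5 falls among 18 (8 and 5 adjusted over the list alone; camera adjusted p = 0.943). The squamous list had 4 rises and 5 falls after median ratio scaling. KRT17 rose from 2175 ± 46.6 to 3181 ± 167 TPM. SERPINB3, a protease inhibitor, fell from 15.6 ± 1.73 to 3.91 ± 0.311 TPM (limma log2 fold change −1.75, SE 0.11, adjusted p = 0.00031). Its reads may be shared with its near copy SERPINB4. Mesenchymal and matrix genes had 9 rises and 3 falls among 23 (10 and 3 adjusted over the list alone; camera adjusted p = 0.044, lost with length and GC trends removed, where adjusted p = 0.07, and adjusted p = 0.203 with an estimated correlation). PLAUR, the urokinase receptor gene, rose from 143 ± 3.54 to 305 ± 19.2 TPM and FN1, which encodes fibronectin, from 1029 ± 27.5 to 1607 ± 29.6 TPM. TGFBI fell from 206 ± 3.49 to 133 ± 4.27 TPM.

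Stress and translation genes changed in part. Of 19 unfolded protein response genes, 11 rose (11 adjusted over the list alone; camera adjusted p = 0.00105, and adjusted p = 0.203 with an estimated correlation). After median ratio scaling the list had 4 rises. The disulfide isomerase gene PDIA3 rose from 432 ± 8.02 to 559 ± 24.9 TPM. Of 23 heat shock and chaperone genes, 6 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 9.33e-06, and adjusted p = 0.343 with an estimated correlation). HSPA8, a constitutive chaperone gene, fell from 888 ± 74.8 to 621 ± 46.1 TPM. After median ratio scaling 12 chaperone genes fell and 0 rose. Of 79 ribosomal protein genes, 17 fell and 5 rose (21 and 9 adjusted over the list alone), with a median log2 fold change of −0.02 (camera adjusted p = 0.000117; adjusted p = 0.452 with an estimated correlation, and 0.831 after quantile normalization). Median ratio scaling gave 22 falls and 2 rises for these. RPLP0, RPL3 and RPL4 fell by 0.62, 0.61 and 0.42 on the log2 scale (SE 0.05, 0.05 and 0.04). ATF4 and amino acid response genes had 6 rises and 5 falls among 26 (9 and 8 adjusted over the list alone; camera adjusted p = 0.334). ATF3 rose from 154 ± 8.11 to 296 ± 17.8 TPM and DDIT3 fell from 268 ± 14.1 to 182 ± 10.9 TPM. The ATF4 list had 3 rises and 8 falls after median ratio scaling. NRF2 target genes had 2 rises and 3 falls among 23 (2 and 3 adjusted over the list alone; camera adjusted p = 0.0298 toward lower levels, and adjusted p = 0.203 with an estimated correlation). The ferritin gene FTH1 rose from 7665 ± 451 to 11851 ± 858 TPM, while PGD and TKT fell, with log2 fold changes of −0.41 and −0.32. The NRF2 list had 2 rises and 4 falls after median ratio scaling.

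The remaining called lists moved by small amounts. CREB-responsive genes had 6 rises and 1 fall among 16 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.239 with an estimated correlation). NR4A2 rose from 37.6 ± 2.74 to 64.6 ± 6.27 TPM and ID2 from 9.05 ± 1.13 to 16.6 ± 0.315 TPM. EGFR ligand and immediate-early genes had 6 rises and 2 falls among 25 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0443, lost in each of the 4 scalings, and adjusted p = 0.531 with an estimated correlation). The feedback inhibitor gene SPRY2 rose from 8.55 ± 0.506 to 15.0 ± 0.490 TPM. Of 15 nuclear and snoRNA host noncoding RNAs, 7 rose (8 adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.343 with an estimated correlation). SNHG7 and SNHG12 rose, with log2 fold changes of 0.67 and 0.89. Cholesterol synthesis genes had 2 rises and 2 falls among 25 (2 and 2 adjusted over the list alone; camera adjusted p = 0.0105 toward lower levels, and adjusted p = 0.239 with an estimated correlation). Median ratio scaling gave 1 rise and 6 falls for cholesterol synthesis genes, 4 rises and 1 fall for CREB-responsive genes, 4 rises and 2 falls for EGFR ligand and immediate-early genes, and 6 rises and 1 fall for the noncoding RNAs.

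Lists without a called test included those closest to the target. Of 27 genes for DHX9 and other double-stranded RNA-binding factors, 5 rose (5 adjusted over the list alone; camera adjusted p = 0.951). The RNA editing enzyme gene ADAR rose from 76.1 ± 7.12 to 102 ± 1.91 TPM and EIF2AK2, the interferon-induced kinase PKR, from 33.8 ± 2.75 to 46.1 ± 3.24 TPM. Of 13 genes near SH3PXD2A-AS1 on 10q, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.716). This was ATP5MD, whose call was lost after median ratio scaling. Of 17 invadopodia genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.81). This was GRB2, whose call was also lost after median ratio scaling, where 1 other member of the list fell. YAP/TEAD target genes had 8 rises and 1 fall among 18 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0511). CCN1, a matricellular protein gene, rose from 941 ± 9.45 to 1251 ± 65.2 TPM. After median ratio scaling the list had 2 rises and 3 falls. Fatty acid genes had 2 rises and 4 falls among 26 (2 and 4 adjusted over the list alone; camera adjusted p = 0.0539). Glycolysis and hypoxia genes had 2 rises and 5 falls among 33 (2 and 5 adjusted over the list alone; camera adjusted p = 0.111). Both lists were called toward lower levels after median ratio scaling, with 1 rise and 7 falls and with 2 rises and 7 falls. Of the double-stranded RNA-binding factor genes 3 rose under this scaling. None of the 31 proteasome genes changed at an adjusted p under 0.05, over all genes or adjusted over the list alone (camera adjusted p = 0.651, and 0.0221 toward lower levels after median ratio scaling, where 2 fell). Ribosome biogenesis and MYC target genes had 4 rises and 2 falls among 29 and splicing factor genes 2 rises and 1 fall among 33 (4 and 2, and 1 and 1, adjusted over the list alone; camera adjusted p = 0.891 and 0.822). These balances reversed after median ratio scaling, to 1 rise and 4 falls for ribosome biogenesis and 0 rises and 4 falls for splicing factor genes. The fatty acid list had a median above 0 and a mean under 0. Camera pointed down for the glycolysis, ATF4, proteasome, 10q, invadopodia, oxidative phosphorylation, splicing, ribosome biogenesis, squamous and DHX9 lists. The median and mean log2 fold change lay above 0 in each of these. Camera compares the test statistics of a list with those of all other genes, not its fold changes with 0. The squamous and ribosome biogenesis medians, at 0.21 and 0.09, even lay above the median of all genes tested, 0.08. Blood, endothelial, fibroblast and neuroendocrine marker lists had fewer than 5 tested members each (2, 1, 3 and 0) and were not tested.

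Among the largest changes, the 10 largest rises were IFI27, RAET1E-AS1, OASL, BST2, IFI6, ISG15, IFIT2, IFNL1, IFNB1 and IFI44L. RAET1E-AS1, an antisense transcript, went from 0.147 ± 0.127 to 15.4 ± 12.6 TPM, the most variable of them between knockdown libraries relative to its mean. The 10 largest falls, besides SERPINB3, PIMREG and PSRC1, were the pseudogenes AL162151.2, AC124856.1 and AC093392.2, NMT1, HSPA6, SCARNA12 and BOLA2. These 7 each lost their call in at least 1 fit with a library left out. All but BOLA2 also lost it without the filter on mean TPM, AL162151.2, NMT1, HSPA6 and SCARNA12 without a trend in the prior spread, and AL162151.2 and AC124856.1 with the replicate number as a block. AL162151.2 lost it as well with a pseudocount of 0.1 and after rescaling without mitochondrial and ribosomal protein genes. All 7 stayed negative in every fit. BOLA2 stood at −0.99 (adjusted p = 0.0508) in the only fit that lost its call, against −1.02 with all libraries. The reads of the pseudogenes, HSPA6 and BOLA2 may be shared with near-identical copies.

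Term enrichment among the changed genes gave 215 terms for rises and 145 for falls out of 3621 tested. Rises included 42 of 58 genes of type I interferon signaling, where 6.82 were expected (one-sided Fisher's exact test, adjusted p = 2.39e-23). Of these 42 IDs, 11 have no gene name. Rises also included 56 of 135 genes of defense response to virus, where 15.9 were expected (adjusted p = 1.34e-15). Falls included 69 of 373 cell division genes, where 14.1 were expected (adjusted p = 4.16e-25), and 23 of 81 genes of chromosome segregation, where 3.06 were expected (adjusted p = 6.28e-12). Of 141 genes of translational initiation, 23 fell, where 5.33 were expected (adjusted p = 4.39e-07). The term for translation initiation factor activity held 11 falls among 74, where 2.80 were expected (adjusted p = 0.0037). The wider term therefore counts other genes too, and its overlap with the ribosomal protein genes that fell was not counted. Terms share genes, so they are not independent. Fisher's test also treats genes as independent draws, so its p-values overstate the evidence where genes of a term move together.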

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

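The number of changed genes depended on the filter, the replicates and the fit, and the split into rises and falls on the scaling. With length and GC trends removed, an alternative chosen after seeing the data, 1110 genes rose and 1152 fell. This fit held 14746 of the 15755 genes and 2210 of the 2327 called, so its counts reflect the smaller set as well as the correction. After median ratio scaling 1012 rose and 996 fell, after quantile normalization 1001 rose and 980 fell, and after rescaling without mitochondrial and ribosomal protein genes 1083 rose and 862 fell; each of these 4 fits moves the median log2 fold change of all genes to near 0, which shifts small changes across the threshold. Without a filter on mean TPM, 1475 genes changed (1136 rose, 339 fell), with more genes tested. Leaving out 1 library at a time gave 1152 to 1633 changed genes, 867 to 1267 rises and 246 to 366 falls, with fewer samples in each fit. The count moved by over 1.5 times without each of the negative control replicates and without knockdown replicates 2 and 3. With the replicate number as a block, 1466 genes changed (1123 rose, 343 fell), but same-numbered libraries did not deviate together (correlations 0.0172, −0.012 and 0.0448), so the numbers give no pairing.

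With an estimated correlation camera called 4 lists in place of 20, and the interferon list, at a median of 1.51, was not called (camera adjusted p = 0.202). The estimate allows for genes of a list moving together. This version of the test also rests on the few residual degrees of freedom of 6 libraries. Calls lost with it may therefore reflect the small design as well. Fry called the G1/S list, at a median of 0.16 (adjusted p = 0.00127), which camera did not, since fry does not compare a list with other genes. Fry also called the YAP/TEAD, cell cycle inhibitor and fatty acid lists (adjusted p = 0.00556, 0.00533 and 0.0455). It did not call the heat shock, ribosomal protein, DNA repair, cholesterol and NRF2 lists (adjusted p = 0.15, 0.187, 0.187, 0.15 and 0.212), which camera called, all toward lower levels. When only called genes that also change at least 2-fold entered, 100 terms were enriched in place of 360. SH3PXD2A-AS1 kept a negative, uncalled change under the alternatives run, from −0.12 to −0.49. Genes named outside the rule, such as MT-ND1, were not recomputed gene by gene. For the 154 that the rule names, 2213 values kept their direction and call, 231 lost the call, 5 gained one and 10 uncalled values changed sign. TPM values keep no depth, so a limit set by depth could not be computed.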

Other observations

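Some genes of antigen presentation rose in knockdown libraries. These genes and those in the next sentences were chosen after their values were seen, except where a list held them. HLA-B, which encodes a class I heavy chain, rose from 26.7 to 82.1 TPM (limma log2 fold change 1.59, SE 0.08), and B2M, the class I light chain, from 2765 to 5632 TPM (1.02, SE 0.06). The term for the MHC class I protein complex held 22 rises among 30 IDs, but 17 of the 22 have no gene name, so the number of distinct loci behind this count is not known. The RNA sensors DDX58 and IFIH1 rose from 11.5 to 35.0 and from 23.7 to 67.7 TPM (limma adjusted p = 0.000856 and 0.000363). The transcription factor genes KLF2 and KLF4 rose from 5.68 to 22.1 and from 12.6 to 44.4 TPM, and TXNIP, which binds thioredoxin, from 91.9 to 312 TPM (limma adjusted p = 0.000537, 0.000111 and 0.000239).

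Some genes of translation initiation fell, as did some ribosomal protein genes. EIF3L, an eIF3 subunit, fell from 182 to 101 TPM (limma log2 fold change −0.84, SE 0.04) and EIF4B from 387 to 235 TPM. EIF3A, EIF3C and EIF3D had smaller falls, with log2 fold changes of −0.37, −0.29 and −0.26, while EIF3B, EIF3K and EIF3M did not pass the test. The term for the eIF3 complex held 7 falls among 18 IDs, where 0.681 were expected (one-sided Fisher's exact test, adjusted p = 0.000177). The noncoding RNA H19 fell from 198 to 113 TPM (limma adjusted p = 0.00297). The share of TPM from genes typed as small nuclear, small nucleolar, small Cajal body, micro, ribosomal or miscellaneous RNA, as ribosomal RNA pseudogenes, or as mitochondrial ribosomal or transfer RNA was 2.30% to 3.18% in control and 1.94% to 1.99% in knockdown libraries. Both of the 2 mitochondrial ribosomal RNA genes tested fell, while none of the 31 small nuclear and 43 miscellaneous RNA genes was called. The lower share may therefore in part restate the fall of mitochondrial RNA.

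What each explanation weighed in the next paragraphs predicts was written after the values that test it were seen, except for words shared by the mitosis genes that fell. Median ratio scaling was fixed before the data were examined, while removal of length and GC trends was chosen afterwards. The real grouping called 2327 genes and the highest of the other splits 2, and the 6 libraries make 10 splits into 3 and 3, of which 1, the real one, reached that number. This is too few for a share under 0.05.

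The rise of interferon-stimulated genes was not removed by scaling. Their median log2 fold change was 1.42 after median ratio scaling, with a lower quartile of 0.94. That scaling takes out a shift that all genes share, and it moved the median of all genes only from 0.08 to −0.002. A shared composition shift was therefore too small to account for the rise. IFNB1 itself rose (log2 fold change 2.67, SE 0.28), so a candidate explanation is sensing of the introduced knockdown reagent or its delivery, whatever the target. A lower SH3PXD2A-AS1 level remains another candidate, and its own difference had an exact permutation p of 0.2. The 2 cannot be told apart, because 1 knockdown group stands against 1 control group and the sources name no second reagent or rescue. Any other difference between the groups, such as in culture, would be confounded in the same way.

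The fall of mitosis genes also outlasted the corrections. Their median log2 fold change was −0.64 after median ratio scaling and −0.60 with length and GC trends removed, against −0.55 as deposited. All 34 members had a GC value, and the second value argues against length or GC bias. The first value was bound to be lower, since that scaling takes out a shift that all genes share, whose median was 0.08. A shared composition shift would have raised these genes, which argues against it as the cause of the fall. If all 30 members that fell held direct sites for 1 shared 7-base seed of the reagent, their annotated 3′ untranslated regions would share a word. The most shared word was in 18 of them and in 52.7% of other genes. It was picked by its count and not by its excess over other genes. This count therefore cannot decide on a seed with sites in only some of the 30. Over 12080 genes no word stood out among falls either, since the lowest z of the search was −3.70 and 55 of 100 permuted searches went as low. An effect of lower SH3PXD2A-AS1, a response to interferon and an off-target effect on a regulator of these genes stay open and were not tested.

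The fall of mitochondrially encoded messages was unequal. Their median log2 fold change was −0.63 after median ratio scaling, which was bound to lower it, since the median of all genes was 0.08. A composition shift that all genes share would have raised these messages, which argues against it as the cause of the fall. Relative to the mean of the 13 genes, 8 changed (limma adjusted p under 0.05), from MT-ND1 at 0.50 (SE 0.03) to MT-CO2 at −0.30 (SE 0.03). This spread argues against 1 lower yield of all mitochondrial RNA as the whole cause. The high value of MT-ND1 lowers the others through the shared mean, so 8 is not a count of separate changes. Poly(A) selection of messages with tails of different length, RNA turnover and transcription stay open and were not tested.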
